A study of Mus musculus with 9 samples.

How the data were processed

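Bone-marrow-derived macrophages of C57BL/6J mice were measured by RNA sequencing, with bones of different animals kept apart so that the replicates are biological, per the labels' protocols. The spinal cord homogenate was made from pooled cords without meninges and was given at 1% weight per volume (10 mg per mL) for 24 h, after 2 h with vehicle, Torin-2 or rapamycin, and the cells were washed before lysis, per the labels' protocols. The doses of both compounds are not given in the sources used here. Libraries were made with the NuGEN Universal Plus mRNA-seq kit and sequenced as paired-end reads of 100 bp, per the labels.

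The deposited values are raw counts per gene, 1 column for each of the 9 samples, and the whole numbers in the table bear this out. Per the submitters' processing notes, the authors used bcl2fastq, FastQC and STAR 2.5.2a with the builds mm10 and GRCm38.p6. The counting tool, the strand setting and the annotation release are not given in the sources used here. Of the 53342 gene identifiers, 53237 were found in GENCODE M21 (GRCm38), 105 were not, and 93.4% of those found had the same symbol there. The table holds 0 genes of the mitochondrial chromosome, so the mitochondrially encoded list, fixed as a sign of RNA quality, was not analysed here.

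Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with edgeR's filterByExpr by group, which left 12511, and libraries were scaled by TMM, with factors from 0.955 to 1.05. One quasi-likelihood fit held all 9 libraries in 3 groups without covariates, and the 3 contrasts were tested 2-sided with Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. The common biological coefficient of variation was 9.96%. With totals of 16116666 to 24044329 counts per library, low-count genes are measured least well. Changes are relative to the other genes because no spike-in was used here. Values are given as CPM, counts scaled to library size and TMM factor, with SD, and fold changes on the log2 scale with SE where printed.

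Lists of genes for pathways, cell types and RNA quality, 37 in all, were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. Of these, 33 had at least 3 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Camera was repeated with an estimated correlation, under which 0 lists were called in each comparison. At an unadjusted p under 0.05 the estimated correlation gave 4, 5 and 3 lists for Torin-2 against vehicle, rapamycin against vehicle and Torin-2 against rapamycin, and limma's fry, which does not compare a list with other genes, called 23, 22 and 23. Of the lists not tested, the lymphocyte markers had 1 tested member, which did not pass in any comparison, and the dendritic, mast and erythroid markers had 0. A list of 6 sex-linked genes served only to check the samples, and the Y-linked Ddx3y stood at 81.9 to 120 CPM in the 9 libraries.

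Named genes were chosen by this rule. For each comparison it takes the 10 largest rises and 10 largest falls among genes that passed, had a mean of at least 5 CPM and did not overlap between groups, leaving out sex-linked genes and symbols of predicted genes, Riken clones and pseudogenes. From each list it takes up to 3 members that rose and 3 that fell among those with at least 1 CPM, of which the text names a few, and it adds 24 genes fixed by name, such as Plin2, Cd36 and Mbp. Some genes that the rule takes, and 1 test of the closing section that needs such a gene, are not reported here.

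Strand is not known, so reads of overlapping genes cannot be told apart. Of 324 named genes tested, 62 overlap another tested gene in GENCODE M21, among them Zfas1 (Znfx1), Pltp (Ctsa), Ctsb (Fdft1), Fbxo32, Slc4a2, Rassf1, Pclaf, Tk1, Ccne2, Cnp, Acss2, Lrp1 and Gadd45a. Their values are uncertain to that extent. Identifiers and positions of the genes that matter most, from GENCODE M21 on GRCm38, are as follows. Plin2 (ENSMUSG00000028494) lies on chromosome 4 from 86648386 to 86670060, Lpl (ENSMUSG00000015568) on chromosome 8 from 68880491 to 68907448, and Cd36 (ENSMUSG00000002944) on chromosome 5 from 17781690 to 17888801. Apoe (ENSMUSG00000002985) lies on chromosome 7 from 19696109 to 19699188, Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915221 to 24927484, and Snhg1 (ENSMUSG00000108414) on chromosome 19 from 8723475 to 8726443. Mmp12 (ENSMUSG00000049723) lies on chromosome 9 from 7344381 to 7369499, Asns (ENSMUSG00000029752) on chromosome 6 from 7675169 to 7693254, and Hmox1 (ENSMUSG00000005413) on chromosome 8 from 75093621 to 75100589.

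Whether the replicate numbers pair the libraries across groups was checked from deviations from the group means. For the 9 same-numbered pairs these correlated at 0.168 to 0.5, against -0.358 to 0.162 for other pairs of different groups, and in 18 of 18 cases a library's best partner in another group had its own number. The numbers were therefore taken to pair the libraries, from the data and not from a statement of the labels. The main fit was fixed before this check and leaves the pairing out, so its p values are those of an unpaired test. The replicate number as a block, among the alternatives below, takes the pairing into account. Replicates differed by more than counting error, with a chi-square per degree of freedom of 5.01 to 60.6 between libraries of a group over 11082 genes.

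The alternatives were edgeR's RLE scaling, library totals alone, no filter on low counts, a stricter filter of 5 CPM in 3 libraries, DESeq2 1.42.0, fits on the 6 libraries of a comparison, a 2-fold minimum, the replicate number as a block, and leaving out each library in turn. Leaving out replicate 3 of every group, and the block together with the estimated correlation, were added after seeing the data.

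The edgeR step was tested on simulated counts for Torin-2 against vehicle, with the 12511 real genes and library sizes. In these counts 200 genes were changed, beside a shifted list of 30, whereas 65.4% of genes were called in the real comparison. The shares recovered therefore hold for the simulated setting only. The edgeR step recovered 65.7% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, and DESeq2 recovered 70.1%, 86.6% and 100%. There were 9 false calls (4.64% of calls). A list of 30 shifted genes was called (camera adjusted p = 7.13e-41, Benjamini-Hochberg), also with adjusted p = 0.000156 with an estimated correlation. By camera, 0 of 30 random lists were called. Genes were drawn independently of each other in these counts. For the real lists of Torin-2 against vehicle, the estimated correlation ran from -0.012 (alternative activation) to 0.666 (cell cycle). The simulated lists therefore cannot show how often the preset correlation would give false list calls in the real counts.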

Results

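RNA was sequenced from mouse bone-marrow-derived macrophages that had been fed homogenised spinal cord, a culture model of the lipid-laden (foamy) macrophages of the injured spinal cord. Cells received vehicle, Torin-2 (an ATP-competitive inhibitor of the mTOR kinase) or rapamycin (an inhibitor of the mTORC1 complex) for 2 h before the homogenate was added at 1% weight per volume for 24 h. Each of the 3 groups held 3 biological replicates, so 9 libraries were compared. Total counts ran from 16116666 in rapamycin replicate 1 to 24044329 in Torin-2 replicate 3. Of 53342 genes in the table, 12511 had enough counts to be tested, and these held 99.92% to 99.94% of the counts of each library. The ferritin heavy chain transcript Fth1 was the most abundant in all 9 libraries, with 3.81% to 5.14% of the counts.

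The treatments separated the libraries far more than the replicates did. The first principal component carried 58.2% of the variance and ran from vehicle through rapamycin to Torin-2, and the second (18.9%) set rapamycin apart from both other groups. Component 3 (9.68%) separated replicate 3 of each group, at -15.2 to -33.8, from replicates 1 and 2, at 8.51 to 13.7. Collagen transcripts were lowest in replicate 3 of each group. Col1a1, a fibroblast collagen, stood at 0.247 CPM in Torin-2 replicate 3 against 0.374 and 0.744 CPM in Torin-2 replicates 1 and 2, at 2.17 CPM in vehicle replicate 3 against 10.1 and 5.78 CPM in vehicle replicates 1 and 2, and at 3.36 against 25.2 and 15.5 CPM with rapamycin.

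**Figure D1:**
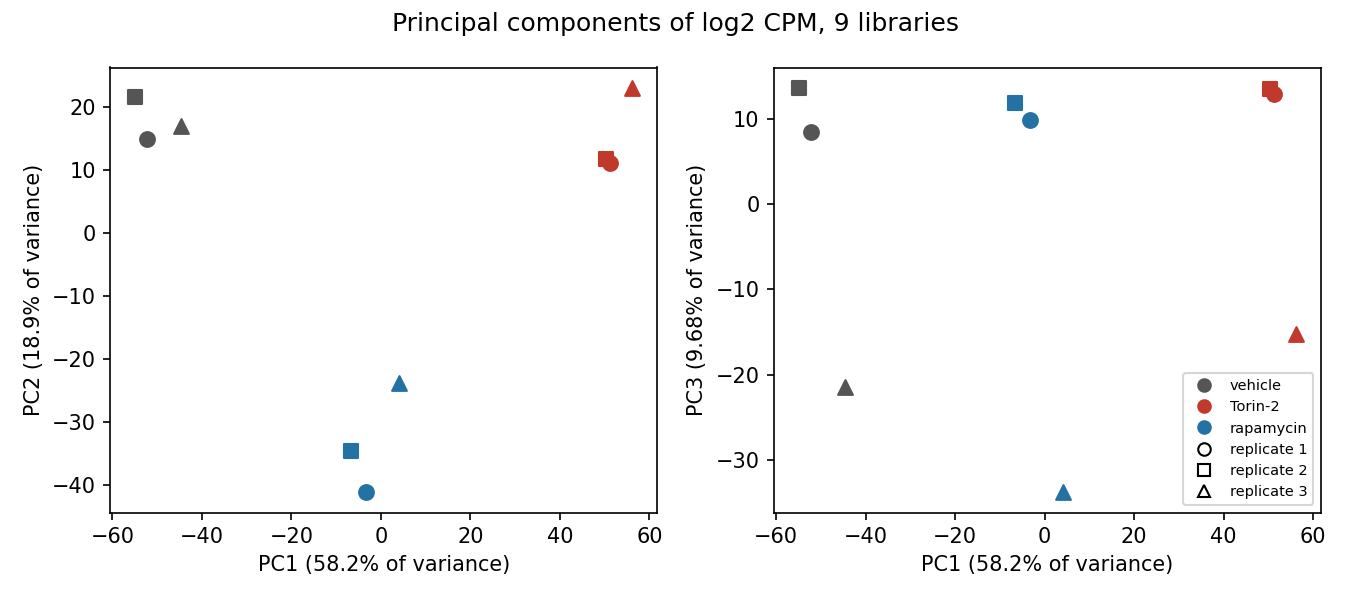
Principal components of the log2 CPM of the genes tested, with component 1 against component 2 (left) and against component 3 (right), in arbitrary units. Each point is 1 library, with the group given by colour and the replicate number by shape. Groups separate along components 1 and 2 (58.2% and 18.9% of the variance), and replicate 3 of each group lies at negative values of component 3 (9.68%).

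Torin-2 against vehicle asks which transcripts differed under the treatment that, per the series design, lowered lipid droplet content. With Torin-2, genes of the endoplasmic reticulum's folding machinery, the respiratory chain, lipid and amino acid synthesis, glycolysis and cell division fell, and ribosomal protein genes, FOXO targets and autophagy genes rose. With an estimated correlation 0 lists were called in this comparison, with a lowest adjusted p of 0.306 (camera, Benjamini-Hochberg). The matrix metalloelastase Mmp12 rose from 858 ± 146 to 16220 ± 881 CPM (mean ± SD, n = 3), and the scavenger protein Cd5l fell from 1142 ± 201 to 12.4 ± 2.41 CPM. In all, 4067 genes were higher and 4115 lower by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, which is 65.4% of the genes tested. Among them, 1266 rose and 1330 fell by at least 2-fold. For 8780 genes (70.2%) every library of one group lay above every library of the other, where chance gives 10% for 3 against 3.

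Of the genes the rule takes, those with the largest rises were host transcripts of small nucleolar RNAs. Snhg1 rose by 6.64 ± 0.22 (log2 fold change ± SE), from 1.01 ± 0.505 to 99.3 ± 5.67 CPM, with an adjusted p of 4.84e-10 by edgeR's quasi-likelihood test (Benjamini-Hochberg). Snhg12, Zfas1 and Snhg5, 3 further such hosts, rose by 6.56, 6.53 and 6.23 on the log2 scale. They were followed by Mamdc2 (6.09), the muscle ubiquitin ligase gene Fbxo32 (5.38), Fam13b (5.18) and the matrix metalloproteinases Mmp8 (4.64), Mmp13 (4.50) and Mmp12 (4.24). Among the largest falls were Cd5l (-6.51), the monocyte chemoattractant Ccl2 (-5.37), the replication genes Pclaf (-4.98) and Rrm2 (-4.31) and the serine synthesis enzyme Psat1 (-4.00). Npl (-3.95), Uhrf1 (-3.93), Col1a1 (-3.77) and the cyclin Ccne2 (-3.75) were also among the largest falls. For Col1a1 the vehicle values are the uneven ones given above, and its adjusted p was 0.00271 by the same test (edgeR, Benjamini-Hochberg). With the replicate number as a block its adjusted p was 2.42e-07 (edgeR, Benjamini-Hochberg).

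Genes that make lipid fell as groups with Torin-2. Of 23 cholesterol synthesis genes tested, 17 fell, 2 rose and 4 did not pass, with log2 fold changes of -2.79 for Hsd17b7 and -2.29 for squalene epoxidase Sqle. Of 16 fatty acid synthesis genes, 11 fell, 3 rose and 2 did not pass. The elongase Elovl6 (-3.76) and the desaturase Scd2 (-2.90, from 97.0 ± 21.3 to 13.0 ± 2.22 CPM) changed most. The camera set test gave Benjamini-Hochberg adjusted p values of 0.00257 and 0.0183 for these lists, and for both lists the adjusted p = 0.306 with an estimated correlation. Single genes of the rule fixed in advance were lower as well, with log2 fold changes of -0.99 for Fasn and -0.79 for Scd1.

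Genes that burn lipid and carry electrons also fell with Torin-2. Of 44 oxidative phosphorylation genes, 40 fell, 0 rose and 4 did not pass, led by cytochrome c (Cycs, -2.19), Atp5g1 (-1.56) and Uqcrq (-1.41). Of 23 fatty acid oxidation genes, 18 fell, 3 rose and 2 did not pass. The trifunctional protein subunit Hadhb had a log2 fold change of -1.49, while Acot2 rose by 0.59 and the carnitine transferase Cpt1a by 0.52. Camera's adjusted p values (Benjamini-Hochberg) were 1.7e-11 and 0.00224, and for both lists the adjusted p = 0.306 with an estimated correlation.

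Genes that store and take up lipid moved in both directions. The droplet coat gene Plin2 fell from 3705 ± 83.6 to 2584 ± 23.4 CPM, a log2 fold change of -0.52 ± 0.05 (SE) with an adjusted p of 3.27e-06 (edgeR, Benjamini-Hochberg). Of 20 droplet and triglyceride storage genes, 11 fell, 6 rose and 3 did not pass. The lipase inhibitor G0s2 (-4.15) and the acyltransferase Gpat3 (-2.88) fell from means of 2.38 and 2.06 CPM, and the lipin Lpin1 (1.09) and the triglyceride lipase Pnpla2 (1.06) rose. Of 15 uptake and scavenger receptor genes, 8 fell, 5 rose and 2 did not pass. Lipoprotein lipase Lpl fell from 1951 ± 187 to 311 ± 51.1 CPM (log2 fold change -2.65) and the scavenger receptor Msr1 from 723 ± 63.7 to 205 ± 15.1 CPM (-1.82), while Cxcl16 (1.47) and Lrp1 (1.12) rose. Camera did not call these lists (Benjamini-Hochberg adjusted p = 0.317 and 0.364). Of 13 LXR target and cholesterol efflux genes, 8 rose, 3 fell and 2 did not pass (camera adjusted p = 0.202, Benjamini-Hochberg). Apoe, an apolipoprotein, rose from 1356 ± 577 to 6548 ± 673 CPM, and the cholesterol exporter Abca1 fell from 1134 ± 20.0 to 811 ± 39.0 CPM. The scavenger receptor Cd36 passed with a log2 fold change of -0.24 and an adjusted p of 0.0292 (edgeR, Benjamini-Hochberg). Its call was lost without vehicle replicate 1 (adjusted p 0.0734), vehicle replicate 2 (0.0749), Torin-2 replicate 1 (0.102) or Torin-2 replicate 3 (0.128). With all libraries and the replicate number as a block, Cd36 had an adjusted p of 0.00365 (edgeR, Benjamini-Hochberg).

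Stress and amino acid genes fell with Torin-2. Of 20 unfolded protein response genes, 18 fell, 0 rose and 2 did not pass, among them the chaperone cofactor Sdf2l1 (-3.30), calreticulin Calr (-2.66) and Creld2 (-2.55). Of 33 ATF4 target and amino acid genes, 26 fell, 5 rose and 2 did not pass. Psat1 fell from 256 ± 19.5 to 16.1 ± 3.46 CPM and asparagine synthetase Asns from 40.4 ± 5.74 to 4.59 ± 0.493 CPM. The transcript of the factor itself, Atf4, rose by 1.54 and that of Ddit3 by 1.51. Of 27 glycolysis and HIF-1 target genes, 20 fell, 3 rose and 4 did not pass, with the prolyl hydroxylases P4ha2 at -2.69 and Egln3 at -1.87. By camera the Benjamini-Hochberg adjusted p values were 2.78e-09, 0.000101 and 3.07e-05 for these lists, and with an estimated correlation the adjusted p values were 0.306, 0.491 and 0.56. The haem oxygenase Hmox1 fell from 10190 ± 70.9 to 2698 ± 584 CPM.

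Growth genes split between ribosomal proteins and the rest. Of 44 ribosomal protein genes, 38 rose, 0 fell and 6 did not pass, among them Rps9 (1.10) and Rps4x (1.05). Of 30 ribosome biogenesis genes, 15 fell, 2 rose and 13 did not pass, with Rrp12 at -1.70 and Bop1 at -1.26 against Npm1 at 1.49. Of 38 cell cycle genes, 33 fell, 2 rose and 3 did not pass, with Rrm2 and Uhrf1 the largest falls and Ube2c (1.50) and the licensing factor Cdt1 (1.24) higher. For these lists camera gave Benjamini-Hochberg adjusted p values of 3.1e-10, 0.0212 and 6.31e-06, and with an estimated correlation the adjusted p values were 0.491, 0.644 and 0.644. Without vehicle replicate 2 the call of ribosome biogenesis was lost (camera adjusted p = 0.0538, Benjamini-Hochberg).

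FOXO target and autophagy genes rose with Torin-2. Of 23 FOXO targets, 18 rose, 4 fell and 1 did not pass. Fbxo32 rose from 10.5 ± 0.284 to 434 ± 15.8 CPM and Cited2 by 4.05 on the log2 scale, and the insulin receptor substrate Irs2 rose by 1.24. The stress-response genes Sesn3 (-2.43) and Sesn1 (-1.74) and the transcription factor Klf2 (-2.13) fell. Of 32 autophagy and TFEB/TFE3 target genes, 22 rose, 5 fell and 5 did not pass, led by Mitf (1.84), Atg2a (1.58) and Atg14 (1.49). Camera's adjusted p values (Benjamini-Hochberg) were 0.000165 and 0.000725, with adjusted p = 0.306 and adjusted p = 0.491 with an estimated correlation. Of 30 PI3K-AKT-mTOR component genes, 15 rose, 8 fell and 7 did not pass, with Deptor at 1.32 and Inpp5d at -0.62. That list was not called (camera adjusted p = 0.0528, Benjamini-Hochberg), but was with the replicate number as a block (0.0479), without vehicle replicate 3 (0.0446) or with no filter on low counts (0.0159), and gave adjusted p = 0.491 with an estimated correlation and 0.463 with that and the block. The pentose phosphate and nucleotide list (15 fell, 5 rose of 24) went from 0.0575 to 0.0458 with the block, to 0.017 without vehicle replicate 3 and to 0.0123 with no filter on low counts, and gave adjusted p = 0.644 with an estimated correlation and 0.58 with that and the block.

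Among the lists of spinal cord cell markers only the oligodendrocyte list was called with Torin-2. Of 11 oligodendrocyte and myelin genes, 8 fell, 0 rose and 3 did not pass, with Cnp at -0.87, Mobp at -0.79 and myelin basic protein Mbp at -0.35 (327 ± 25.1 against 418 ± 52.6 CPM). The list's call (camera adjusted p = 0.0451, Benjamini-Hochberg) gave adjusted p = 0.644 with an estimated correlation. It was also lost without vehicle replicate 2 (0.111), vehicle replicate 3 (0.0517), Torin-2 replicate 1 (0.0699), 2 (0.0705) or 3 (0.0596), or rapamycin replicate 3 (0.0553). Of 16 macrophage markers, 5 rose and 6 fell (camera adjusted p = 0.873, Benjamini-Hochberg), with Cd14 at 2.69 and Fcgr1 at -1.42. Adjusted over the list alone, the counts of all lists given for this comparison were equal to those over all genes, except that 1 oxidative phosphorylation gene and 16 PI3K-AKT-mTOR genes rose.

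**Figure D2:**
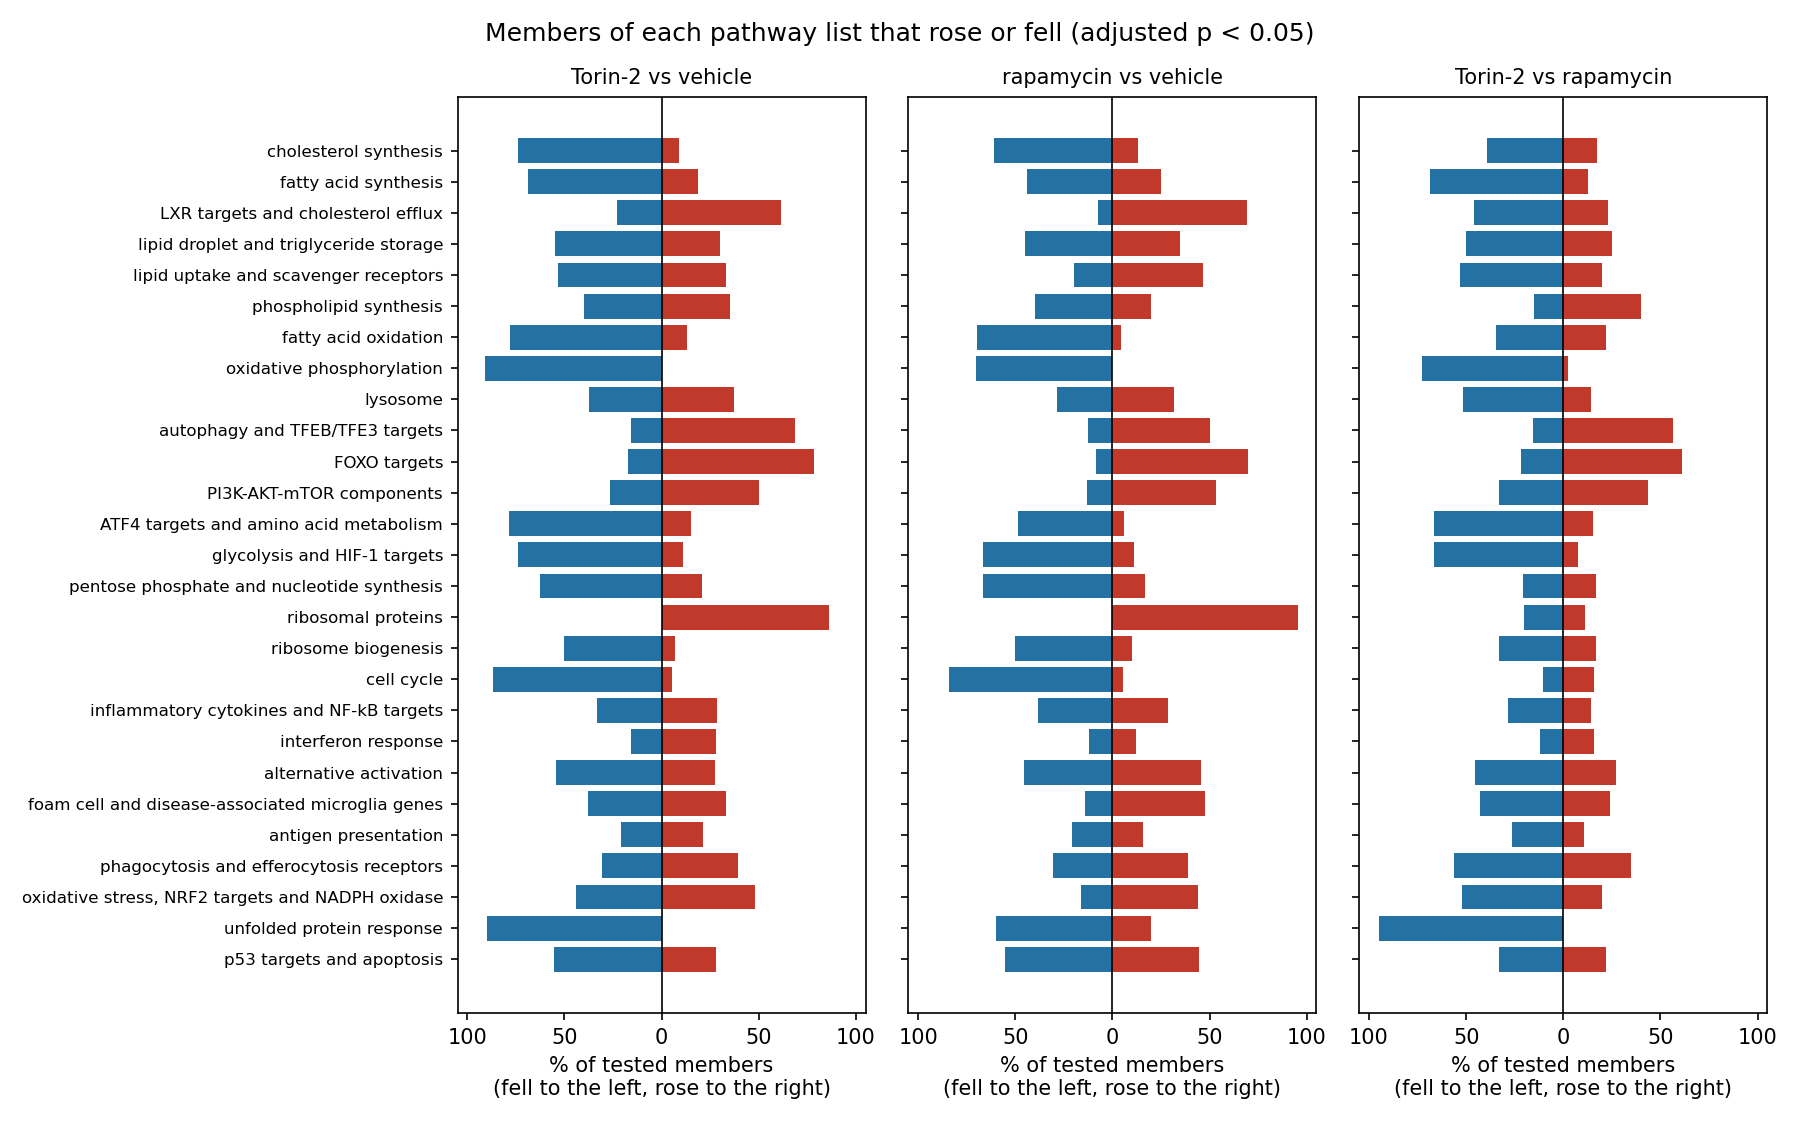
Share of the tested members of each pathway list that rose (red, to the right) or fell (blue, to the left) at an adjusted p under 0.05, in percent, for Torin-2 against vehicle, rapamycin against vehicle and Torin-2 against rapamycin. Of 44 oxidative phosphorylation genes, 40, 31 and 32 fell in these comparisons, and of 44 ribosomal protein genes 38, 42 and 5 rose.

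Rapamycin against vehicle asks what inhibition of mTORC1 changed, since the series design states that rapamycin left lipid accumulation as it was. Ribosomal protein, FOXO target, LXR target and macrophage marker genes rose with rapamycin, and genes of cell division, the respiratory chain, fatty acid oxidation and cholesterol synthesis fell. The estimated correlation left 0 lists called, with a lowest adjusted p of 0.32 (camera, Benjamini-Hochberg). Arginase Arg1 rose from 31.6 ± 3.29 to 554 ± 232 CPM and the phospholipid transfer protein Pltp from 85.5 ± 18.1 to 657 ± 30.3 CPM. By edgeR's quasi-likelihood test 3078 genes were higher and 3273 lower (Benjamini-Hochberg adjusted p under 0.05, 50.8% of those tested), and 432 rose and 644 fell by at least 2-fold. The groups did not overlap for 7191 genes (57.5%, where chance gives 10%). Scaled by library totals alone, 2421 genes were higher and 4046 lower, so that the higher share of the calls was 37.4% in place of 48.5%.

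The 10 largest rises with rapamycin, with Riken clones and predicted genes left out by the rule, were Fbxo32 (log2 fold change 4.35), Arg1 (4.13), the nuclear receptor Nr4a1 (3.99), Zfas1 (3.57), Mmp13 (3.39), the lipopolysaccharide co-receptor Cd14 (3.29), Mmp12 (3.22), Snhg12 (2.95), Pltp (2.94) and the caveolin Cav1 (2.71). Arg1 had a standard error of 0.37 and an adjusted p of 4.77e-06 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Among the largest falls were Ccl2 (-6.46), Pclaf (-3.62), the thymidine kinase Tk1 (-3.55), Uhrf1 (-3.24), Ccne2 (-3.18), Mcm5 (-3.08), Npl (-3.01), the receptor Cd300lf (-2.97) and Rrm2 (-2.88). Ccl2 fell from 30.1 ± 8.59 to 0.339 ± 0.0762 CPM.

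Lipid genes moved apart with rapamycin. Of 23 cholesterol synthesis genes, 14 fell, 3 rose and 6 did not pass, with Hsd17b7 at -2.44, Sqle at -1.37 and the regulator Srebf2 at 0.48. Of 16 fatty acid synthesis genes, 7 fell, 4 rose and 5 did not pass, with Elovl6 at -1.92 and Fasn at -1.34. Of 13 LXR target and efflux genes, 9 rose, 1 fell and 3 did not pass, with Pltp at 2.94 and Apoe at 1.98. Camera's Benjamini-Hochberg adjusted p values were 0.0057, 0.492 and 0.00163, and for the first and last of these lists adjusted p = 0.32 and adjusted p = 0.351 with an estimated correlation. Of 20 droplet and storage genes 9 fell and 7 rose (camera adjusted p = 0.669, Benjamini-Hochberg), and of 15 uptake genes 7 rose and 3 fell (0.305). Plin2 fell to 2838 ± 32.6 CPM (log2 fold change -0.39), while Cd36 rose from 8898 ± 534 to 13730 ± 882 CPM (0.63) and Lpl from 1951 ± 187 to 3251 ± 116 CPM (0.74). The fatty acid binding proteins Fabp4 (-1.51) and Fabp5 (-1.50) fell. For Abca1 the log2 fold change was -0.04, with an adjusted p of 0.642 (edgeR, Benjamini-Hochberg).

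Energy and growth genes changed largely as groups. Of 44 oxidative phosphorylation genes 31 fell, 0 rose and 13 did not pass, led by Atp5g1 (-1.04) and Cyc1 (-0.81). Of 23 fatty acid oxidation genes 16 fell, 1 (Cpt1a, 0.34) rose and 6 did not pass. Of 44 ribosomal protein genes 42 rose, 0 fell and 2 did not pass, among them Rps4x (1.03) and Rpl37 (0.94). Camera's Benjamini-Hochberg adjusted p values were 2.65e-08, 0.000647 and 1.96e-18, and for all 3 lists the adjusted p = 0.32 with an estimated correlation. Of 38 cell cycle genes 32 fell and 2 rose, of 27 glycolysis and HIF-1 targets 18 fell and 3 rose, and of 24 pentose phosphate and nucleotide genes 16 fell and 4 rose. Examples are Tk1, lactate dehydrogenase Ldha (-1.01) and thymidylate synthase Tyms (-2.09). Camera gave Benjamini-Hochberg adjusted p values of 4.52e-09, 0.000233 and 0.0136, and for all 3 lists the adjusted p = 0.545 with an estimated correlation. Of 30 ribosome biogenesis genes 15 fell and 3 rose, with Rrp12 at -0.83 and the transcription factor Myc at 1.06 (camera adjusted p = 0.0162, Benjamini-Hochberg). That call gave adjusted p = 0.565 with an estimated correlation, and 0.077 without replicate 3 of every group, an alternative chosen after seeing the data.

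Signalling, stress and marker lists moved with rapamycin too. Of 23 FOXO targets 16 rose and 2 fell, of 30 PI3K-AKT-mTOR components 16 rose and 4 fell, and of 32 autophagy and TFEB/TFE3 targets 16 rose and 4 fell. Cited2 (2.70), the mTOR-binding Deptor (0.89) and Mitf (1.30) were among the risers, and the catalytic subunit Pik3cd rose by 0.56. Camera's Benjamini-Hochberg adjusted p values were 8.54e-06, 0.00781 and 0.00163, and with an estimated correlation the adjusted p values were 0.32, 0.351 and 0.532. Of 33 ATF4 targets 16 fell and 2 rose, with Psat1 at -2.39 and Asns at -0.71, and of 20 unfolded protein response genes 12 fell and 4 rose, with Sdf2l1 at -1.51 and the chaperone Hspa5 at -1.07. Their camera adjusted p values (Benjamini-Hochberg) were 0.00432 and 0.000594, with adjusted p = 0.545 and adjusted p = 0.517 with an estimated correlation. Of 16 macrophage markers 10 rose and 3 fell, with Cd14 at 3.29, Itgam at 0.72 and Adgre1 at -0.43 (camera adjusted p = 0.0057, Benjamini-Hochberg, and adjusted p = 0.525 with an estimated correlation). Single myelin transcripts rose beside them, with Mbp at 613 ± 67.7 against 418 ± 52.6 CPM (0.55) and Mobp at 0.66. The oligodendrocyte list as a whole (3 rose, 2 fell of 11) was not called (camera adjusted p = 0.428, Benjamini-Hochberg). Adjusted over the list alone, the counts of the lists given for rapamycin against vehicle were equal to those over all genes, except that 8 uptake genes, 17 autophagy genes, 17 PI3K-AKT-mTOR genes and 11 macrophage markers rose and 17 pentose phosphate and nucleotide genes fell.

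Torin-2 against rapamycin is the direct contrast, in which the series design uses rapamycin to control for inhibition of mTORC1. Relative to rapamycin, unfolded protein response, respiratory chain, ATF4 target, glycolysis and fatty acid synthesis genes were lower with Torin-2, and autophagy genes were higher. None of these list calls held with an estimated correlation, where the lowest adjusted p of the comparison was 0.348 (camera, Benjamini-Hochberg). Lpl stood at 311 ± 51.1 CPM with Torin-2 against 3251 ± 116 CPM with rapamycin, Cd36 at 7554 ± 776 against 13730 ± 882 CPM, and Msr1 at 205 ± 15.1 against 733 ± 38.5 CPM. By edgeR's quasi-likelihood test 3025 genes were higher and 3010 lower (Benjamini-Hochberg adjusted p under 0.05, 48.2% of those tested), and 647 and 552 of them differed by at least 2-fold. Scaled by library totals alone, 3635 genes were higher and 2456 lower, and the higher share of the calls was 59.7% in place of 50.1%. The groups did not overlap for 7154 genes (57.2%, where chance gives 10%).

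Of the genes the rule takes, those most in favour of Torin-2 were Snhg1 (6.81), Snhg5 (4.99), Fam13b (4.13), Rassf1 (3.64), Snhg12 (3.61), Mamdc2 (3.52), the interleukin-1 receptor antagonist Il1rn (3.48), Slc4a2 (3.27), Mmp8 (3.18) and Zfas1 (2.95). Snhg1 had 99.3 ± 5.67 CPM with Torin-2 and 0.842 ± 0.4 CPM with rapamycin (adjusted p 4.79e-09 by edgeR's quasi-likelihood test, Benjamini-Hochberg). Among the genes lower with Torin-2 were Col1a1 (-5.03), Cd5l (-4.02), Cytip (-4.01), Arg1 (-3.67), Lpl (-3.39), Nr4a1 (-3.08), Klf2 (-2.99), Col1a2 (-2.97) and Asns (-2.43). Lpl had a standard error of 0.12 and an adjusted p of 4.79e-09 (edgeR, Benjamini-Hochberg).

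Among the lipid lists only fatty acid synthesis was called in the direct contrast, and with no filter on low counts phospholipid synthesis was called as well (camera adjusted p = 0.035, Benjamini-Hochberg, against adjusted p = 0.584 with an estimated correlation). Of 16 fatty acid synthesis genes 11 were lower, 2 higher and 3 did not pass, with Scd2 at -2.37 and Acss2 at -1.89 (camera adjusted p = 0.00678, Benjamini-Hochberg, and adjusted p = 0.348 with an estimated correlation). Of 15 uptake genes 8 were lower, 3 higher and 4 did not pass, with log2 fold changes of -3.39 for Lpl, -2.08 for Olr1, -1.84 for Msr1 and -0.86 for Cd36 (camera adjusted p = 0.135, Benjamini-Hochberg). Of 23 cholesterol synthesis genes 9 were lower and 4 higher, of 20 droplet and storage genes 10 were lower and 5 higher, and of 23 fatty acid oxidation genes 8 were lower and 5 higher. Their camera adjusted p values were 0.222, 0.243 and 0.212 (Benjamini-Hochberg). Scd1 (-1.30) and Abca1 (-0.45) were lower with Torin-2. For Plin2 the log2 fold change was -0.14 ± 0.05 (SE), with an adjusted p of 0.0506 (edgeR, Benjamini-Hochberg) that became 0.0482 with the replicate number as a block and 0.0406 without vehicle replicate 2. It was 0.000896 with DESeq2, 0.0404 with RLE scaling and 0.0266 with the 6 libraries of the comparison alone. For Fasn it was 0.36 ± 0.15 (SE) with an adjusted p of 0.0732 (edgeR, Benjamini-Hochberg), and 0.00911 with the block, 0.0484 without Torin-2 replicate 3, 0.0173 without rapamycin replicate 2, 0.038 with library totals alone and 0.00288 with no filter on low counts. For Apoe it was 0.29 ± 0.22 (SE) with an adjusted p of 0.298 (edgeR, Benjamini-Hochberg), and 0.0417 without vehicle replicate 3, 0.0288 with the 6 libraries of the comparison alone and 0.000193 with no filter on low counts.

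Folding, energy and degradation genes differed between the compounds. Of 20 unfolded protein response genes 19 were lower, 0 higher and 1 did not pass, with the chaperone Hyou1 at -1.79 and Sdf2l1 at -1.79. Of 44 oxidative phosphorylation genes 32 were lower, 1 (Sdha, 0.20) higher and 11 did not pass, with Cycs at -1.49. Of 33 ATF4 targets 22 were lower and 5 higher, and of 27 glycolysis and HIF-1 targets 18 were lower and 2 higher. In camera the Benjamini-Hochberg adjusted p values were 8.83e-14, 9.36e-09, 0.000564 and 9.07e-05, and with an estimated correlation the adjusted p values were 0.348 for the first pair and 0.584 for the second. Of 35 lysosome genes 18 were lower and 5 higher, with cathepsins Ctsl at -1.20 and Ctsb at -0.78 against the proton pump subunit Atp6v0d2 at 1.54. Of 32 autophagy and TFEB/TFE3 targets 18 were higher and 5 lower, with Optn at 0.98 and Rragd at 0.88, and of 23 FOXO targets 14 were higher and 5 lower, with the growth arrest gene Gadd45a at 2.13. Camera's adjusted p values (Benjamini-Hochberg) were 0.0304, 0.0148 and 0.0395, and with an estimated correlation the adjusted p values were 0.586, 0.584 and 0.584. The lysosome call was lost without rapamycin replicate 3 (0.0662), and the FOXO call without Torin-2 replicate 1 (0.0519) or rapamycin replicate 2 (0.0558). Ribosomal protein genes (5 higher, 9 lower of 44) and cell cycle genes (6 higher, 4 lower of 38) were not called (camera adjusted p = 0.637 and 0.741, Benjamini-Hochberg).

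Markers of cells also differed between the compounds, and moved with the groups above. Of 11 oligodendrocyte and myelin genes 9 were lower with Torin-2, 0 higher and 2 did not pass, with Mobp at -1.45 and Mbp at -0.91. Of 10 astrocyte genes 8 were lower and 0 higher, with S100b at -1.42 and Gfap at -1.28. Of 16 macrophage markers 11 were lower and 2 higher, with the chemokine receptor Cx3cr1 at -4.04 and Fcgr1 at -1.07. Cx3cr1 had few reads, with raw counts in replicates 1 to 3 of 7, 3 and 6 with Torin-2 and 85, 116 and 42 with rapamycin. It also overlaps the tested genes Csrnp1, Gorasp1 and Wdr48. The camera test gave Benjamini-Hochberg adjusted p values of 0.00458, 0.0161 and 0.0054, and for these lists the adjusted p = 0.584 with an estimated correlation. Of 8 fibroblast and endothelial genes 3 were lower and 1 (Vwf, 2.01) higher (camera adjusted p = 0.715, Benjamini-Hochberg). Adjusted over the list alone, the counts of the lists given for this comparison were equal to those over all genes, except that 3 fatty acid synthesis, 6 ATF4 target and 6 lysosome genes were higher, 4 cell cycle genes were higher, and 12 fatty acid synthesis, 11 droplet, 19 lysosome and 12 macrophage genes were lower.

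**Figure D3:**
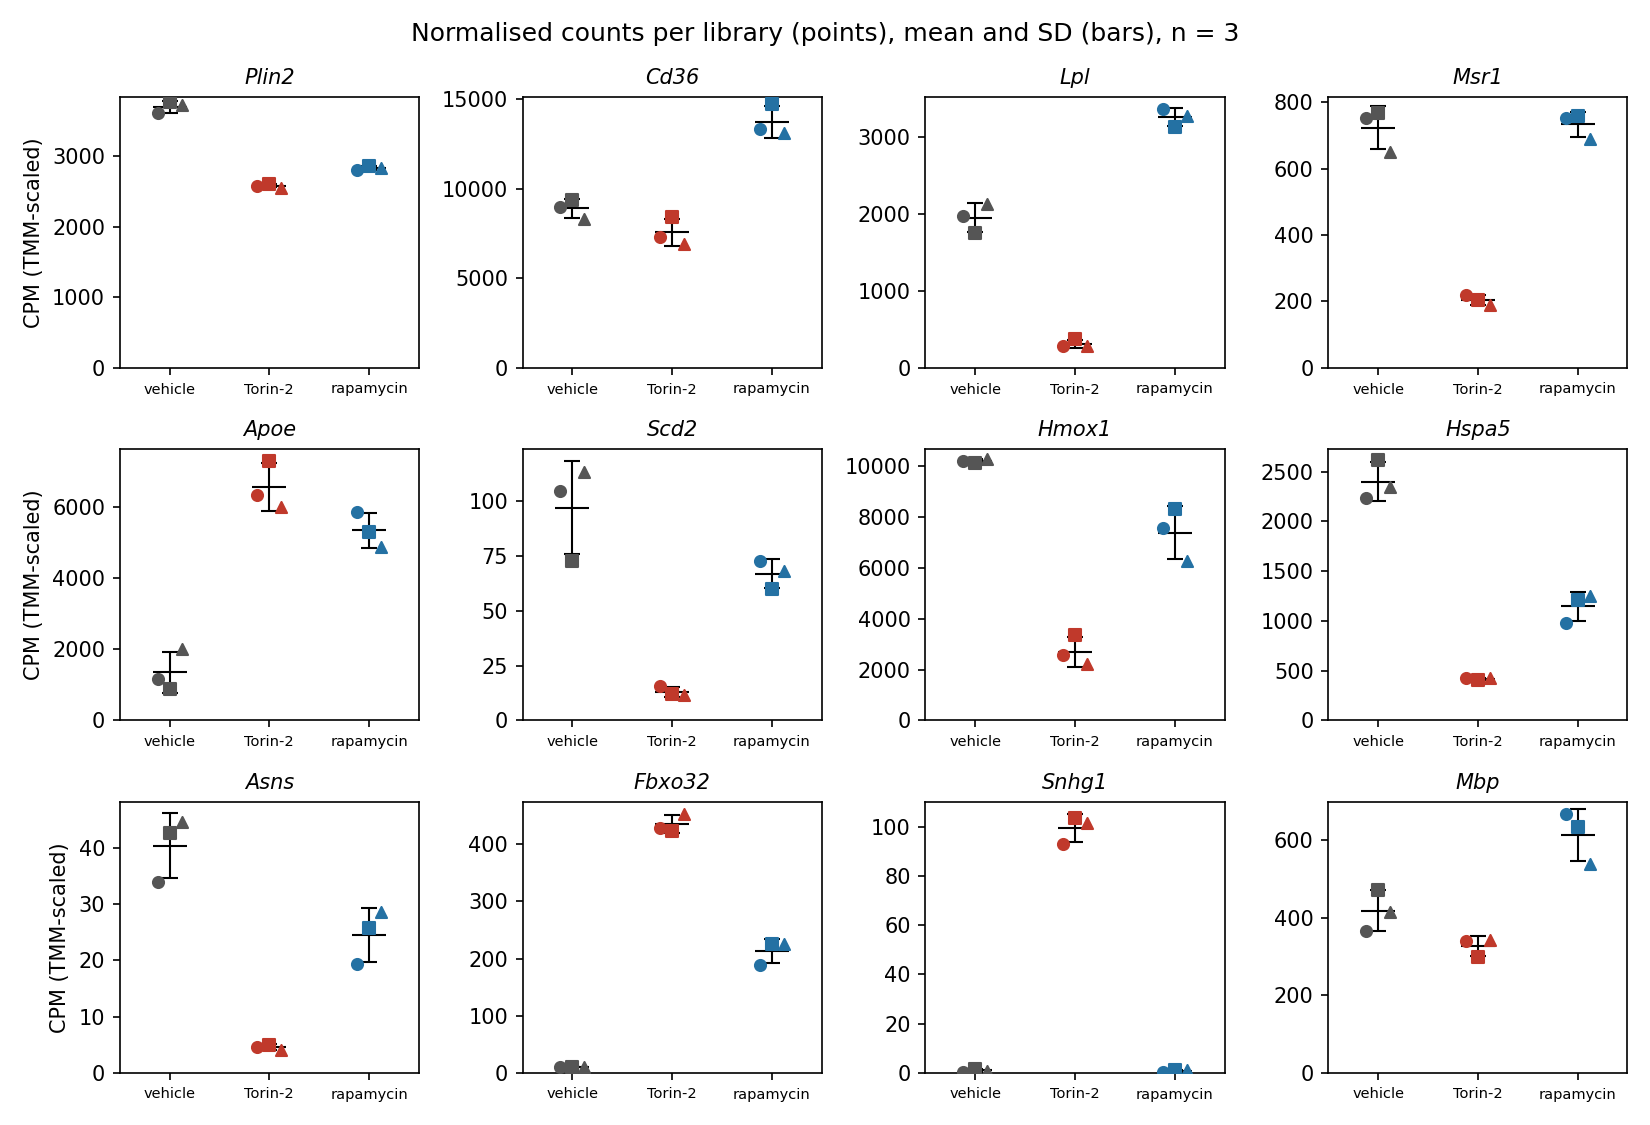
Normalised counts (CPM after TMM scaling, linear axes from 0) of 12 genes in each library, by treatment. Points are libraries (circle, square and triangle for replicates 1, 2 and 3), and the bars give the mean and SD of the group (n = 3). Plin2 was lower than vehicle (3705 CPM) with both compounds, and with Torin-2 Lpl and Msr1 had means of 311 and 205 CPM.

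Both compounds were set against the same vehicle libraries, so their calls were also compared with each other. Genes higher with both numbered 2347 and genes lower with both 2614, where independent lists of these lengths would share 1001 and 1077. In 50 simulations, unchanged groups were set against 1 shared vehicle group, with libraries drawn independently and without the pairing of replicate numbers. At most 2 calls were shared, but unchanged groups give few calls of any kind. The simulations therefore do not show how many shared calls the shared controls would add among genes with real changes. The covariance of the log2 fold changes across genes was 0.454, against 0.0317 in the simulations, a difference of 0.422. Across genes, which are not independent replicates, the correlation was 0.69 against a simulated 0.488. The 3 vehicle libraries cannot be split into groups of 2, so part of the excess of shared calls over independent lists may come from the shared controls. Of the 4961 genes that changed in the same direction, 3728 (75.2%) changed more with Torin-2, with a median ratio of 1.4, and 2411 (48.6%) did not pass in the direct contrast.

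Opposite changes were found for 279 genes. All 279 also passed in the direct contrast, which is no separate support, since that contrast is the Torin-2 change minus the rapamycin change. Lpl, Klf2 and the adaptor Cytip fell with Torin-2 (-2.65, -2.13 and -1.33) and rose with rapamycin (0.74, 0.86 and 2.68). The stress gene Gadd45b rose with Torin-2 (2.16) and fell with rapamycin (-0.77). Gadd45b was singled out after its values were seen.

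**Figure D4:**
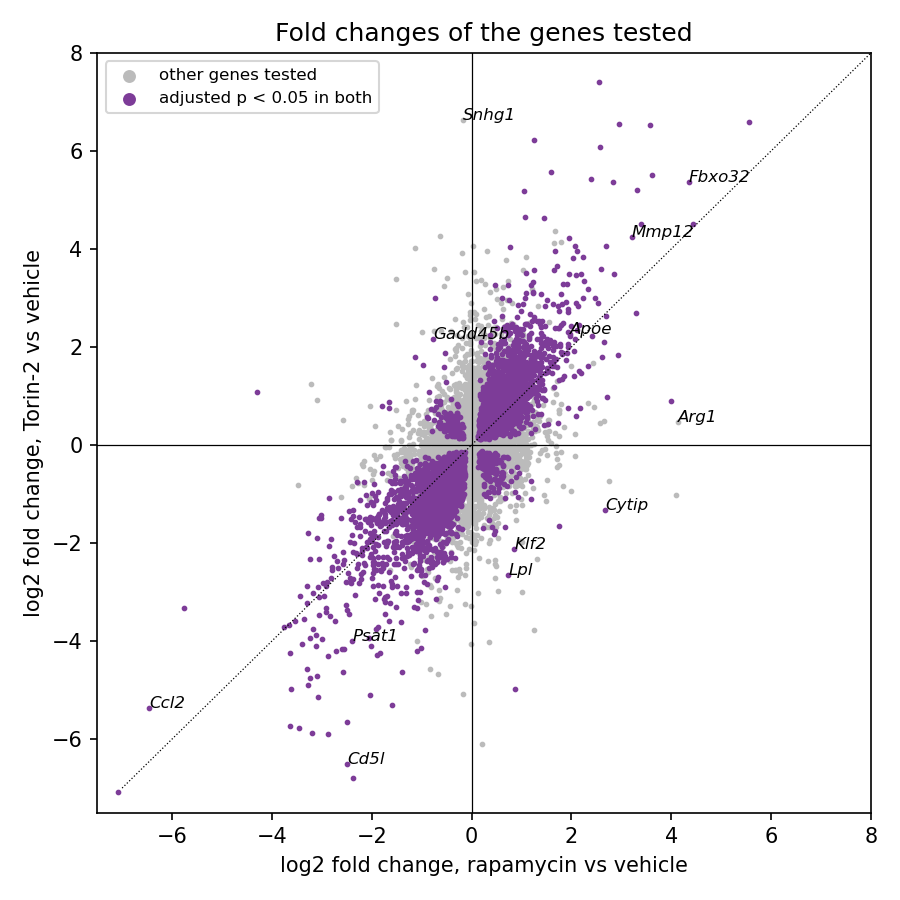
Log2 fold change against vehicle with rapamycin (horizontal axis) and with Torin-2 (vertical axis) for the 12511 genes tested. Purple points passed in both comparisons, grey points did not, and the dotted line marks equal change. Genes such as Lpl and Cytip lie in the lower right, and Fbxo32, Mmp12 and Apoe in the upper right.

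Other genes of the rule fixed in advance gave weaker or uneven differences. Il1b, Il6 and Nos2 had too few counts to be tested, and Tnf did not pass against vehicle with Torin-2 (adjusted p = 0.265, edgeR, Benjamini-Hochberg) or rapamycin (0.234). Arg1 with Torin-2 had a log2 fold change of 0.46 with an adjusted p of 0.269 (edgeR, Benjamini-Hochberg), 0.0374 without Torin-2 replicate 3 and 8.04e-09 with no filter on low counts. Its raw counts in replicates 1 to 3 were 931, 1119 and 543 with Torin-2 and 826, 608 and 620 with vehicle. The groups thus overlapped, and the value without a filter is doubtful. Other values given with no filter on low counts call for the same caution. The mannose receptor Mrc1 fell with rapamycin (-1.33) and was higher with Torin-2 than with rapamycin (1.01), and Gpnmb was higher with Torin-2 than with rapamycin (0.67). Hmox1 with rapamycin had -0.47 and an adjusted p of 0.0138 (edgeR, Benjamini-Hochberg), and 0.053 without rapamycin replicate 3. Scd1 with rapamycin had 0.52 and 0.0171, and 0.0747 without vehicle replicate 1 or 0.0674 without rapamycin replicate 1. Mtor with Torin-2 had -0.30 and 0.0214, and lost its call without vehicle replicate 1 (0.0761) or 3 (0.0795) or Torin-2 replicate 1 (0.0724) or 2 (0.0699). With all libraries and the replicate number as a block, Scd1 with rapamycin had 0.0115 and Mtor with Torin-2 had 0.00293 (edgeR, Benjamini-Hochberg). For rapamycin the log2 fold change of Mtor was -0.03 (adjusted p = 0.827, edgeR, Benjamini-Hochberg). Mki67, a proliferation marker, fell with Torin-2 (-2.03) and rapamycin (-1.40), and Torin-2 against rapamycin gave -0.63 (adjusted p = 0.138, edgeR, Benjamini-Hochberg).

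Further calls of these genes depended on single libraries in fits without the replicate number as a block. Each is given with its adjusted p (edgeR, Benjamini-Hochberg) with all libraries and without the library named. With Torin-2 against vehicle, Gpnmb (0.34, 0.0231) had 0.0752 without vehicle replicate 2, 0.0704 without Torin-2 replicate 1 and 0.0515 without Torin-2 replicate 2. Mrc1 (-0.32, 0.0191) had 0.0852 without vehicle replicate 1, 0.0544 without vehicle replicate 2 and 0.0845 without Torin-2 replicate 3. With rapamycin against vehicle, Gpnmb (-0.33, 0.0336) had 0.0951 without vehicle replicate 1, 0.118 without vehicle replicate 3, 0.052 without Torin-2 replicate 1, 0.131 without rapamycin replicate 2 and 0.0859 with the 6 libraries of the comparison alone. With the block and all libraries, Gpnmb and Mrc1 with Torin-2 had 0.00206 and 0.00057, and Gpnmb with rapamycin had 0.0046 (edgeR, Benjamini-Hochberg). Fits with the block and a library left out were not run.

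In the direct contrast, Tnf (-1.02, adjusted p = 0.037 by edgeR, Benjamini-Hochberg) had 0.103 without Torin-2 replicate 1, 0.131 without Torin-2 replicate 3, and 0.0869, 0.0576 and 0.072 without rapamycin replicates 1, 2 and 3. Mtor (-0.27, 0.0472) had 0.0602 without vehicle replicate 1, 0.13 and 0.135 without Torin-2 replicates 1 and 2, and 0.16 and 0.0771 without rapamycin replicates 1 and 3, and 0.114 with library totals alone. Pik3cd (-0.23, 0.039) had 0.0527 without vehicle replicate 1, 0.0521, 0.146 and 0.0553 without Torin-2 replicates 1, 2 and 3, and 0.143 and 0.0573 without rapamycin replicates 1 and 3, and 0.127 with library totals alone. Irs2 did not pass (0.25, 0.174) but did without rapamycin replicate 1 (0.0116) and with no filter on low counts (0.0191). Sesn3 (-0.71) and Hmox1 (-1.45) were lower with Torin-2 than with rapamycin whichever library was left out.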

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

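Of 99 list results and 579 named gene results, 0 went from a call in one direction to a call in the other. These list results were compared one by one under the block, the estimated correlation, no filter and left-out libraries only. With RLE scaling only the number of lists called was compared, at 13, 15 and 11, as in the main fit. Library totals alone, the stricter filter, DESeq2 and the fits on 6 libraries were compared for genes alone. The direction of lists that were not called did change in places, as for antigen presentation in the direct contrast with the block and for cell cycle genes there with fry. Of 9794 named gene values under the alternatives, 233 changed side of the threshold (211 lost, 22 gained, in 65 results), most often when 1 library was left out, and of 1386 list values 106 did (90 lost, 16 gained), most of them with the estimated correlation. Leaving out 1 library at a time gave, for Torin-2 against vehicle, 3705 to 4167 genes higher and 3790 to 4223 lower. For rapamycin against vehicle it gave 2595 to 3039 higher and 2850 to 3235 lower, and for Torin-2 against rapamycin 2586 to 3094 and 2582 to 3084. Genes changed in the same direction by both compounds then numbered 4277 to 4825, and lists called 11 to 14, 15 to 17 and 10 to 11. A minimum of 2-fold left, as its construction implies, 1266 and 1330 genes higher and lower for Torin-2 against vehicle, 432 and 644 for rapamycin, 647 and 552 in the direct contrast, and 758 shared. With an estimated correlation 0 lists were called in each comparison, with the lowest adjusted p values at 0.306, 0.32 and 0.348 (camera, Benjamini-Hochberg), and with the block as well at 0.463, 0.402 and 0.666, while fry called 23 for Torin-2 against vehicle and 23 for Torin-2 against rapamycin. The camera runs differ in the correlation setting, 0.01 when preset and -0.012 to 0.666 when estimated for Torin-2 against vehicle. Fry does not compare a list with other genes. How far these differences moved single lists was not tested. Scaling by library totals alone moved the median log2 fold change of all genes from 0.001 to -0.095 for rapamycin against vehicle and from -0.001 to 0.073 for Torin-2 against rapamycin. In simulated counts for Torin-2 against vehicle, 65.7% of genes changed 1.5-fold were recovered, the lowest share of the changes simulated. Only 200 genes were changed there, beside a shifted list of 30, whereas 65.4% of genes were called in the real comparison. That share therefore does not carry over to the real counts.

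With the replicate number as a block, counts of higher and lower genes became 4354 and 4359 (Torin-2 against vehicle), 3462 and 3541 (rapamycin against vehicle) and 3378 and 3453 (Torin-2 against rapamycin), with 5427 shared. Of the calls made without the block, 8168 of 8182, 6338 of 6351 and 6027 of 6035 kept their direction and call. The pairing changed 2 list calls and 3 named genes, given in the results where those genes are reported, and no other list or named gene. Without replicate 3 of every group, an alternative chosen after seeing the data, 3997 and 3992 genes were higher and lower for Torin-2 against vehicle, 2997 and 3153 for rapamycin against vehicle and 2904 and 2844 in the direct contrast, with 4688 shared and 13, 15 and 11 lists called. It then gave camera adjusted p values (Benjamini-Hochberg) of 0.0508 for oligodendrocyte markers and 0.0221 for pentose phosphate and nucleotide genes with Torin-2 against vehicle and 0.00886 for foam cell genes with rapamycin.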

Other observations

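Genes of immune function moved within lists that were not called as a whole. Of 21 inflammatory genes, 6 rose and 7 fell with Torin-2 and 6 rose and 8 fell with rapamycin, where Il1rn rose 3.52 on the log2 scale with Torin-2 (108 ± 17.7 to 1240 ± 235 CPM) and Cd40 fell (-2.04). Of 23 phagocytosis and efferocytosis receptor genes, 9 rose and 7 fell with each compound against vehicle. The Fc receptor Fcgr2b rose by 3.00 with Torin-2 and 1.08 with rapamycin, and the complement gene C1qa fell (-2.66 and -1.02). Of 11 alternative activation genes 3 rose and 6 fell with Torin-2, and 5 rose and 5 fell with rapamycin. The transcription factor Egr2 rose with both (3.00 and 2.47), and Folr2 fell with both (-2.52 and -0.86). Of 21 foam cell and disease-associated microglia genes 7 rose and 8 fell with Torin-2, and 10 rose and 3 fell with rapamycin, with Mmp12 the largest rise in both. Camera's Benjamini-Hochberg adjusted p values against vehicle with Torin-2 were 0.581, 0.865, 0.581 and 0.8 for these lists, and with rapamycin 0.669, 0.434, 0.916 and 0.0823. The last was 0.0497 without vehicle replicate 1 and 0.0171 without vehicle replicate 3, and 0.0155 with no filter on low counts, but adjusted p = 0.701 with an estimated correlation.

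Of 25 oxidative stress genes 12 rose and 11 fell with Torin-2, with the oxidase subunit Cybb at 1.23 and the peroxiredoxin Prdx6 at -1.59, and 11 rose and 4 fell with rapamycin (camera adjusted p = 0.873 and 0.0777, Benjamini-Hochberg). The rapamycin value was 0.0376 without vehicle replicate 3, 0.0401 without rapamycin replicate 1 and 0.0217 with no filter on low counts, but adjusted p = 0.545 with an estimated correlation. Of 35 lysosome genes 13 rose and 13 fell with Torin-2 and 11 rose and 10 fell with rapamycin (0.736 and 0.669). Of 20 phospholipid synthesis genes 7 rose and 8 fell with Torin-2, led by Cds2 (1.34), and 4 rose and 8 fell with rapamycin (0.8 and 0.669). Of 25 interferon response genes 7 rose and 4 fell, and 3 rose and 3 fell (0.607 and 0.743). Of 19 antigen presentation genes 4 rose and 4 fell, and 3 rose and 4 fell (0.8 and 0.994). Of 18 p53 and apoptosis genes 5 rose and 10 fell, and 8 rose and 10 fell, with Bbc3 up (2.03 and 1.19) and Phlda3 down (-2.52 and -1.36) with both compounds (0.451 and 0.786). In the direct contrast these lists gave camera adjusted p values (Benjamini-Hochberg) of 0.135 for oxidative stress and phospholipid synthesis (0.035 for each with no filter on low counts and 0.584 for each with an estimated correlation), 0.637 for interferon response and inflammation, 0.819 for antigen presentation, 0.589 for p53, 0.36 for phagocytosis, 0.473 for alternative activation and 0.222 for foam cell genes. Of the other marker lists, astrocyte, neuron, fibroblast and endothelial, and granulocyte genes gave 0.196, 0.736, 0.736 and 0.489 with Torin-2 against vehicle and 0.33, 0.182, 0.743 and 0.244 with rapamycin. Neuron and granulocyte genes gave 0.135 and 0.36 in the direct contrast, as LXR targets (0.222), PI3K-AKT-mTOR components (0.39), pentose phosphate and nucleotide genes (0.715) and ribosome biogenesis (0.384) were also not called there. Adjusted over the list alone, 9 inflammatory genes fell and 3 antigen presentation genes rose with Torin-2 against vehicle. With rapamycin against vehicle 5 phospholipid synthesis and 12 oxidative stress genes rose, 5 oxidative stress and 4 foam cell genes fell, 2 interferon response genes rose, and 2 antigen presentation genes rose and 3 fell. All other counts of this section were equal. Median and mean log2 fold change had opposite signs for the lysosome, phagocytosis, oxidative stress, macrophage and foam cell lists with Torin-2, and for the inflammatory and alternative activation lists with rapamycin. They did so in the direct contrast for the LXR, inflammatory, pentose phosphate, ribosome biogenesis, antigen presentation and granulocyte lists.

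For the patterns that follow, the test of the Col1a1 to Mbp ratio, the bootstrap intervals and the count of hosts without an overlapping gene were chosen only after the values were seen, and the patterns were found in the same data. The bootstrap drew genes of a list anew and the permutation relabelled genes, not libraries. Genes of the same libraries are not independent replicates, so neither measures the spread between libraries. The first is that noncoding hosts of small nucleolar RNAs were higher with Torin-2 than with vehicle, with 16 of 24 rising (median 2.43), against a median of 0.30 with rapamycin. Leaving out the 6 hosts seen first, 10 of 18 rose and 3 fell, one of them Cct6a, which the annotation lists as a processed transcript, and the median of 1.52 lay above all 10000 lists of long noncoding genes matched on expression. Those lists had a median of 0.294 (95% of them -0.253 to 0.75), which argues against unspliced or nuclear RNA being counted more as the whole cause. Noncoding hosts rose by 1.438 more than the 218 protein-coding hosts (1-sided permutation p = 1e-05, the smallest that 100000 permutations can give). This met the bound set for slower decay of transcripts with untranslated exons. However, the protein-coding median was 0.084, so the difference largely restates the rise of the noncoding hosts. Decay was not measured, and any cause particular to noncoding hosts would give the same difference. The test therefore does not single out slower decay. Reads of overlapping genes cannot be told apart for the 6 of these hosts that overlap a tested gene (median of those genes 0.685, between the bounds set), but of the 12 that overlap none 6 rose and 2 fell.

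The second pattern is that oligodendrocyte and astrocyte markers were lower with Torin-2 than with rapamycin (for both lists adjusted p = 0.584 with an estimated correlation). An independent list of 50 central nervous system genes moved likewise, with a median log2 fold change of Torin-2 against rapamycin of -0.789 (95% bootstrap interval over genes -1.033 to -0.568). Of its 39 tested genes 36 lay below 0, 16 fell and 0 rose. Against vehicle its median was -0.44 with Torin-2 and 0.512 with rapamycin. RNA carried over from the homogenate could give such a shift. However, the mesenchymal list below moved the same way and further (-1.471 in the direct contrast), so the shift was not particular to central nervous system genes. Ckb (173 CPM), among the more abundant members of the central nervous system list, was lower than vehicle with both compounds (-1.58 and -0.84). None of the 50 genes is in the lists fixed earlier and 1 is in the mesenchymal list below. Cells without homogenate were not analysed here, so how many of the 50 genes macrophages express stays open. Whether uptake, clearance or washing differed between treatments stays open as well.

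The third pattern is that collagen transcripts were lower with Torin-2 than with rapamycin, with a median of -3.67 for Col1a1, Col1a2 and Col3a1. RNA carried over from the homogenate would keep Col1a1 in a steady ratio to Mbp, but the log2 ratio had an SD of 2.06, close to the 2.38 of Col1a1 alone. Fewer mesenchymal cells in the Torin-2 cultures cannot be told apart from a change in expression. An independent list of 35 mesenchymal genes (1 of them in an earlier list, 1 in the list above) had all 31 tested members below 0, of which 13 fell. Its median was -1.471, nearer 0 than the bound of -1.84, with an interval over genes (-1.936 to -0.959) that includes the bound. By the rule as first written, without the interval, the list would count against fewer mesenchymal cells as the explanation. Against vehicle its median was -0.728 with Torin-2 (1 rose, 7 fell) and 0.715 with rapamycin (2 rose, 0 fell). By these medians the difference between the compounds was not a fall with Torin-2 alone. With rapamycin, however, only 2 of the 31 tested members passed, and genes of the same libraries are not independent. The most abundant members, among them Fn1 (79.9 CPM), are also made by macrophages in part, and the labels name no sort of the cells.

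Other splits of the libraries were counted for each comparison, with the third group kept in place. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For Torin-2 against vehicle, rapamycin against vehicle and Torin-2 against rapamycin the real splits called 8182, 6351 and 6035 genes and the highest of the others 0 in each case, so that 1 split reached the real count. For lists the real splits gave 13, 15 and 11 and the highest others 13, 17 and 12, with 4, 2 and 2 of the 10 splits as many. Every other split puts 2 libraries of 1 treatment with 1 of the other. The treatment difference then enters the spread within each side, which makes 0 gene calls near certain. A part of it also stays between the sides, so the lists called there are not calls without a treatment difference. The splits therefore cannot show how many genes or lists chance alone would call. Of the 9 other splits, 3 part all 3 pairs of replicate numbers, as the real split does, and gave 10 to 13, 7 to 13 and 4 to 12 lists, and the 6 that part 1 pair gave 9 to 13, 7 to 17 and 4 to 10.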
